A study of Mus musculus with 18 samples.

How the data were processed

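Total RNA (100 ng per sample) from 18 microdissected mouse lung tumours was amplified, labelled with biotin and hybridised to single-colour arrays, per the labels' protocols. The authors deposited log2 signals per probe set that were made with GCRMA 2.20.0 in R 2.11.0, per the submitters' processing notes. GCRMA corrects background by probe sequence, quantile normalises the arrays and summarises probes by median polish, so differences in total RNA between tumours are removed before deposit. Other filters, scan dates and batches are not given in the sources used here. The log2 scale was checked on the values, which ran from 0.936 to 14.1 with none missing. No 2 arrays were duplicates: correlations ran from 0.975 to 0.997.

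The table held 22690 probe sets, of which 20380 had 1 gene symbol, 691 had several, 1555 had none and 64 were controls. Of the probe sets with 1 symbol, 20351 matched the reference table by gene ID and 0 symbols changed. Probe sets with several symbols or none were named for no gene, and genes whose probe sets carry no single symbol, the restored gene among them, are not reported here. Each of 12393 genes was represented by its probe set with the highest mean over the arrays; 4956 genes had 2 or more probe sets. Genes above the array median on at least 4 arrays were tested, which left 7300. Groups held 4 or 6 tumours, so a gene could pass this filter through a single group in which it was high. A shared direction of list members may thus be partly set by the filter.

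Groups were taken from the labels (treated or untreated, grade 3 or grade 2), with the tumour as the replicate and the mouse as a random block. limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 18 tumours, with a correlation of 0.259 between tumours of a mouse, 14 residual and 3.8 prior degrees of freedom. Fitted differences weight tumours by this correlation and can differ from plain differences of group means, as for Xist (5.27 fitted in grade 3). The 5 comparisons were treatment in each grade, their interaction, and grade in untreated and in treated tumours, with Benjamini-Hochberg adjustment and a threshold of 0.05. P-values over tumours are too small, because tumours of a mouse are not independent. Of 29 gene lists, 27 had at least 3 measured members beside the sex check and were tested with camera (preset correlation 0.01), camera with the correlation estimated from the data, and fry, adjusted over the lists of a comparison. The erythroid and platelet list had too few measured members. No list call in any comparison held with the estimated correlation. List means per tumour were compared with two-sided exact permutation tests over tumours and over animal means. Animal means were taken within each group, so mice 8565 and 8688 each gave a mean in both grades.

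The design, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Cdkn1a, Mdm2 and Cdkn2a always, up to 2 passing members per list, and the 5 highest and 5 lowest passing differences without overlap between groups, or, where nothing passed, the 5 smallest p-values. It let list members that did not pass be named with their values. Anln, Cdc20 and the sex genes were named outside the rule, after their values were seen. Leaving out each untreated mouse, 2 tumours with a 3' excess or the 2 least correlated tumours was added after seeing the data. Alternatives were no animal term, animal as a fixed block, animal means, sex as a covariate, only the groups compared, a further quantile normalisation or median centring, no filter, a floor of log2 5 on 4 arrays, the mean of a gene's probe sets, no shared probe sets, another spread model, array weights, a log2 threshold of 1, and leaving out tumours. Treatment could not be estimated with animal as a fixed block, since no mouse carried treated and untreated tumours.

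RNA quality was read from the 3' minus 5' signal of 4 control transcripts, as set before the values were seen. After seeing them, the mean over the 2 transcripts whose 5' probe sets lay above the array median on every array was added; it was highest in 8688T3 at 2.62 and 8639T4 at 1.85, against 1.05 or less in the others.

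The steps were tested on simulated values for the 7300 genes with the animal structure of the study. For treatment in grade 3, 31.3%, 86.6% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 12 false calls among 156. For treatment in grade 2 the shares were 25.4%, 80.6% and 93.9%, with 14 false calls among 147, and for grade in untreated tumours 34.3%, 95.5% and 100%, with 11 among 164. For the interaction they were 16.4%, 70.1% and 97%, with 3 false calls among 125, and for grade in treated tumours 46.3%, 94% and 98.5%, with 8 among 167. The share of false calls thus exceeded the nominal rate in some comparisons. The animal correlation was estimated at 0.186 to 0.194, below the simulated 0.26. With no change simulated, 0 or 1 genes and 0 lists were called. Simulated genes were drawn independently of each other, so the 0 lists say nothing of false calls for lists whose members vary together.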

Results

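Gene expression was measured on single-colour oligonucleotide arrays in 18 lung tumours microdissected from 6 mice of a mixed C57/B6 and 129SvJae background, aged 10 weeks. Per the labels, treated mice received tamoxifen in 2 injections, which restored p53 in their tumours, and tumours were collected on day 7 after the first injection. Tumours were graded, which gave 6 treated grade 3, 4 treated grade 2, 4 untreated grade 3 and 4 untreated grade 2 tumours. Signals are log2 values with array medians between 6.05 and 6.18, and the number of arrays limits their precision. All 6 treated grade 3 tumours and 3 of the 4 treated grade 2 tumours came from the female mouse 8688. The remaining treated grade 2 tumour, 8639T4, came from a male mouse, and all 8 untreated tumours came from the males 8565, 8584, 8629 and 8700. Treatment therefore cannot be told apart from animal and sex in grade 3, and nearly so in grade 2. Tumours of one mouse are not independent, so p-values computed over tumours are too small. The sex genes matched the labels: Xist, the transcript of the inactive X chromosome, had a mean of 11.53 ± 0.25 (SD, n = 6) in treated grade 3 and 5.03 ± 0.50 (SD, n = 4) in untreated grade 3 tumours. The Y-linked gene Eif2s3y had means of 1.85 ± 0.19 (SD, n = 6) and 11.32 ± 0.51 (SD, n = 4) in the same groups. The gene that was restored is not analysed here.

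The first comparison asked what p53 restoration changed in grade 3 tumours. As lists, genes of mitosis and of a gut-like programme were lower in the treated tumours, and p53 target, interferon and alveolar genes were higher, by camera with a preset correlation. None of these list calls held with an estimated correlation (adjusted p from 0.0843 to 0.651), and few single members passed. Cdkn1a, which encodes the cell cycle inhibitor p21 and is a direct p53 target, had a mean log2 signal of 11.15 ± 0.52 (SD, n = 6) in treated and 9.48 ± 0.63 (SD, n = 4) in untreated tumours. The groups did not overlap, but the fitted log2 difference of 1.53 (SE 0.43, limma adjusted p = 0.151) did not pass over all genes. When 1 tumour was left out, Cdkn1a passed only without the untreated tumour 8584T3, with a difference of 1.90. Mdm2, which encodes the ubiquitin ligase that restrains p53, differed by 0.40 (SE 0.20, adjusted p = 0.592). Cdkn2a, which encodes the p53 activator ARF, lay below the array median on every array, with 5.02 ± 0.53 (SD, n = 6) in treated and 5.53 ± 0.41 (SD, n = 4) in untreated tumours, and was not tested.

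As a list, the p53 targets rose in treated grade 3 tumours, with a median log2 difference of 0.39 over 31 measured members and 24 members above 0 (camera adjusted p = 1.49e-06). The call was lost with the correlation between members estimated from the data (adjusted p = 0.213 with an estimated correlation). None of the members passed over all genes, and 9 passed when adjusted over the list alone. These were Cdkn1a, the cyclin gene Ccng1 with 0.80 (SE 0.20), Phlda3 with 1.52 (SE 0.38), Zmat3 with 1.05 (SE 0.35), Plk2 with 1.03 (SE 0.31), Psrc1 with 3.76 (SE 1.05), the death receptor gene Fas with 0.74 (SE 0.26), Aen with 0.65 (SE 0.23) and the repair gene Ercc5 with 0.60 (SE 0.15). The mean signal of the list per tumour was 9.39 ± 0.17 (SD, n = 6) in treated and 8.83 ± 0.14 (SD, n = 4) in untreated tumours, without overlap. The difference of 0.56 had p = 0.00476 in a two-sided exact permutation test over tumours, the smallest p the 210 splits allowed. It was 0.0267 after Benjamini-Hochberg adjustment over the lists, with the sex check counted among them. The alveolar type 1, gut, immediate early and sex check lists had the same 2 values. The sex check parts the female mouse 8688 from the males, so this p does not single out the p53 targets. With 1 treated against 3 untreated mice, the exact p over animal means was 0.25, which is the smallest that design can give.

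**Figure D1:**
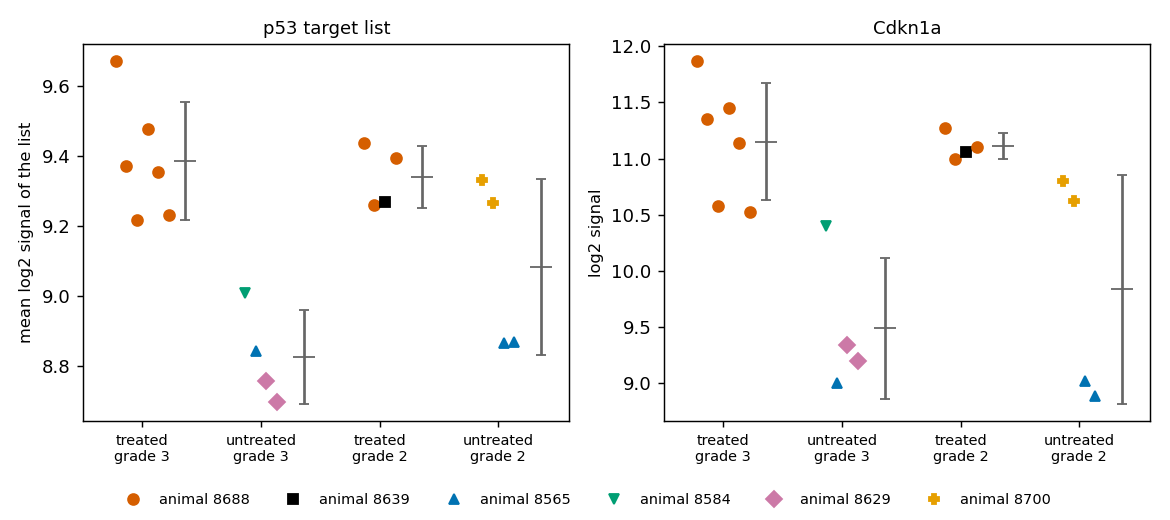
Mean log2 signal of the p53 target list (left) and log2 signal of Cdkn1a (right) in each tumour, by group. Each point is a tumour, coloured and shaped by mouse, and the grey bar beside each group is the mean ± SD. The 2 untreated grade 2 tumours of mouse 8700 lie at 9.33 and 9.26 on the left panel, and those of mouse 8565 lie at 8.87.

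The mitosis list fell by a median of 1.40 on the log2 scale in treated grade 3 tumours, and all 18 measured members were lower (camera adjusted p = 1.87e-27; adjusted p = 0.0843 with an estimated correlation). The mean signal of the list differed by -1.37 (two-sided exact permutation p = 0.0143 over tumours), which did not pass after Benjamini-Hochberg adjustment over the lists (0.0667), and the untreated tumour 8584T3, at 6.62, lay within the treated range of 6.12 to 6.87. Of 34 members fixed in advance 18 passed the filter on low values. A member could do so through the untreated tumours alone, so the shared direction may be partly set by the filter. Of the measured members 3 passed over all genes and 17 when adjusted over the list alone. Nusap1, which encodes a spindle protein, fell by 2.00 (SE 0.42, adjusted p = 0.0438), Cdca3 fell by 1.70 (SE 0.32, adjusted p = 0.0217) and Cdc20, which activates the anaphase-promoting complex, fell by 1.51 (SE 0.32, adjusted p = 0.0438). The cytokinesis gene Anln, outside the list, fell by 1.62 (adjusted p = 0.00186). The proliferation marker Mki67 differed by -1.33 (SE 0.38, adjusted p = 0.159) and Cdk1 by -1.54 (SE 0.43, adjusted p = 0.144). The DNA replication list fell by a median of 0.32 (camera adjusted p = 0.000113; adjusted p = 0.35 with an estimated correlation). Of its 18 members only the thymidine kinase gene Tk1 passed, and it fell by 1.41 (SE 0.30, adjusted p = 0.0447). Without 8629T12 the median of the list was -0.17. The calls of Nusap1 and Tk1 were lost without any 1 of the grade 3 tumours other than 8688T5 and 8584T3, and that of Cdca3 without 8565T1 or 8629T12.

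Genes of the gut, stomach and embryo that mark advanced lung tumours fell as a list by a median of 1.65 over 6 members, all lower (camera adjusted p = 6.19e-08; adjusted p = 0.0843 with an estimated correlation). The galectin gene Lgals4 fell by 1.91 (SE 0.29, adjusted p = 0.00483) and the claudin gene Cldn2 fell by 1.40 (SE 0.30, adjusted p = 0.0438). Adjusted over the list alone, 4 members passed. Only 6 of the 24 members fixed in advance passed the filter on low values. A member could do so through the 4 untreated grade 3 tumours alone, so the shared direction may be partly set by the filter. The call of Cldn2 was lost without 8688T1, 8688T3, 8688T5, 8688T6, 8688T11, 8629T10 or 8629T12. Hnf4a, a transcription factor of liver and gut epithelium, differed by -3.79 (SE 0.90, adjusted p = 0.072). Muc5b, a secreted mucin gene, fell by 3.06 (SE 0.46, adjusted p = 0.00483), from 6.93 ± 0.68 (SD, n = 4) in untreated to 3.78 ± 0.75 (SD, n = 6) in treated tumours. The immediate early and dissociation list fell by a median of 0.27 (camera adjusted p = 0.00319; adjusted p = 0.342 with an estimated correlation), and none of its 17 members passed. With sex as a covariate its direction turned, to a median of 0.15 (camera adjusted p = 0.863).

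The interferon response list rose by a median of 0.49, with 20 of 20 members higher (camera adjusted p = 8.59e-07; adjusted p = 0.35 with an estimated correlation). Ifit3 rose by 1.99 (SE 0.39, adjusted p = 0.0279), and 9 members passed when adjusted over the list alone. The untreated tumour 8565T1, at a list mean of 8.13, lay within the treated range of 7.80 to 8.46, and without it the median was 0.97. The alveolar type 1 list rose by a median of 0.37, with 10 of 10 members higher (camera adjusted p = 0.000113; adjusted p = 0.151 with an estimated correlation). Rtkn2, a marker of alveolar type 1 cells, rose by 1.95 (SE 0.25, adjusted p = 0.0015), and Hopx differed by 0.79 (SE 0.21, adjusted p = 0.118). Adjusted over the list alone, 3 type 1 members passed. The alveolar type 2 list, which holds the surfactant genes, rose by a median of 0.25 with all 17 members higher (camera adjusted p = 0.0323; adjusted p = 0.651 with an estimated correlation), and no member passed. That call was lost without 8688T1 (0.23), 8584T3 (0.11) or 8629T12 (0.26). Ephx1, which encodes an epoxide hydrolase, rose by 2.36 (SE 0.48, adjusted p = 0.0377), while its drug metabolism list did not pass (median 0.44, camera adjusted p = 0.0516). The calls of Ifit3 and Ephx1 were lost without 8688T1, 8688T3, 8629T10 or 8629T12. With fry, the p53 target, mitosis, alveolar type 1 and gut lists passed, at adjusted p of 0.0292, 0.0152, 0.0131 and 0.0131.

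**Figure D2:**
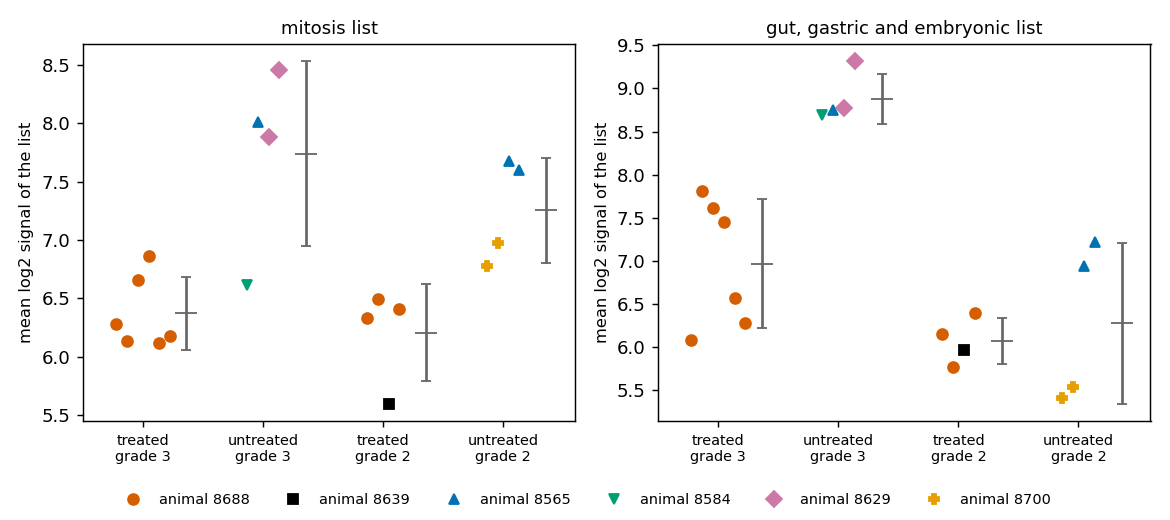
Mean log2 signal of the mitosis list (left) and of the gut, gastric and embryonic list (right) in each tumour, by group. Each point is a tumour, coloured and shaped by mouse, and the grey bar is the mean ± SD. The mitosis list lies at 6.37 ± 0.31 (SD, n = 6) in treated grade 3 and at 7.74 ± 0.79 (SD, n = 4) in untreated grade 3 tumours.

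In all, 34 of 7300 genes passed in grade 3, 14 higher and 20 lower in treated tumours, and 645 had an unadjusted p under 0.05. Besides the genes above, rises were seen in the ribonuclease gene Ang3 at 3.74 (SE 0.79), Dglucy at 2.61 (SE 0.48), the transcription elongation gene Ctr9 at 2.51 (SE 0.39) and Cth, which encodes the cysteine-forming enzyme cystathionine gamma-lyase, at 2.13 (SE 0.34). The rise of Ctr9 was seen in 1 of its 4 probe sets, while the others, which lay below the array median on nearly every array, differed by 0.22, -0.07 and 0.04. Falls were seen in Scara3, which fell by 3.23 (SE 0.63), the adult beta-globin gene Hbb-b2, which fell by 3.09 (SE 0.38), and Fam160b1, which fell by 1.98 (SE 0.34). Ang3 did not follow treatment in the male treated tumour: it was 6.70 ± 0.20 (SD, n = 6) in treated grade 3, 2.13 ± 0.16 (SD, n = 4) in untreated grade 3 and 2.14 in 8639T4, and with sex as a covariate its difference was -0.40. The lower group mean of Ang3, Muc5b, Hnf4a, Scara3, Dglucy, Nusap1, Cdca3, Cdk1, Tk1, Anln, Phlda3 and Psrc1 lay below the array median, so the sizes of these differences are not exact. The call of Ang3 was lost without any 1 of the grade 3 tumours other than 8688T5 and 8584T3, that of Scara3 without 8688T1 or 8629T12 and that of Dglucy without 8688T3. The count was 10 with sex as a covariate, of which 6 were among the 34, 272 without the animal term and 0 on animal means. The sex term stood for mouse 8688, the only female, so the first of these counts rests on 8639T4. Leaving out 1 tumour gave 19 genes without 8688T1, 16 without 8688T3, 16 without 8629T12 and 168 without 8584T3.

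Other lists did not pass in grade 3. Senescence and secreted factors had a median of -0.11 (camera adjusted p = 0.0786), regulators of the ARF-p53 pathway -0.05 (0.582), MAPK output -0.04 (0.119), club and ciliated genes -0.61 (0.0552), epithelial to mesenchymal genes -0.19 (0.102) and apoptosis machinery -0.05 (0.504). Epithelial junction genes had a median of 0.01 (camera adjusted p = 0.992). Among markers of other cell types, macrophage genes had a median of 0.09 (0.992), neutrophil genes 0.16 (0.756), T and NK cell genes -0.17 (0.504), B and plasma cell genes -0.37 (0.228), fibroblast genes -0.01 (0.348) and endothelial genes 0.28 (0.0633). The median was 0.22 for antigen presentation (0.467), 0.19 for oxidative and NRF2 genes (0.236), 0.18 for sterol synthesis (0.128), 0.03 for hypoxia and glycolysis (0.504) and 0.25 for ribosomal proteins (0.0786). The camera direction was down for neutrophil and hypoxia genes and up for the ARF-p53 list, against the sign of the median.

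The second comparison asked the same of grade 2 tumours. The mitosis list fell here too, by a median of 1.09 with all 18 members lower (camera adjusted p = 2.88e-19; adjusted p = 0.16 with an estimated correlation). None of its members passed over all genes, and 16 passed when adjusted over the list alone. The mean signal of the list was 6.21 ± 0.41 (SD, n = 4) in treated and 7.26 ± 0.45 (SD, n = 4) in untreated grade 2 tumours, a difference of -1.05 (two-sided exact permutation p = 0.0286, 0.16 after Benjamini-Hochberg adjustment). That p is the smallest the 70 splits allowed. The epithelial to mesenchymal, fibroblast, antigen presentation and sex check lists had the same 2 values, so it does not single out mitosis. Over animal means the exact permutation p was 0.333, the smallest that design can give. The p53 target list did not pass, with a median of 0.10 and 16 of 31 members above 0 (camera adjusted p = 0.0925). Adjusted over the list alone, 2 members passed: Trp53inp1 at 0.68 (SE 0.19) and Aen at 0.87 (SE 0.24).

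Cdkn1a was 11.11 ± 0.12 (SD, n = 4) in treated and 9.83 ± 1.02 (SD, n = 4) in untreated grade 2 tumours, a fitted difference of 1.24 (SE 0.44, adjusted p = 0.51). The untreated values parted by mouse: Cdkn1a was 10.80 and 10.63 in the tumours of 8700 and 9.02 and 8.88 in those of 8565. The p53 target list did likewise, with animal means of 9.30 in 8700 and 8.87 in 8565, against 9.36 for the treated grade 2 tumours of 8688 and 9.27 for 8639T4. Without mouse 8700, an alternative added after these values were seen, the list's median was 0.19 (camera adjusted p = 0.000393), and without mouse 8565, added likewise, it did not pass and lay below 0. When 1 tumour was left out it passed without 8688T9, 8700T1 or 8700T3, with medians of 0.12, 0.14 and 0.12, and not without any of the other 5, of which 8565T3 turned the median to -0.037. Mdm2 differed by -0.01 (SE 0.21, adjusted p = 0.994). Cdkn2a was 4.86 ± 0.79 (SD, n = 4) in treated and 4.24 ± 0.38 (SD, n = 4) in untreated grade 2 tumours.

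Antigen presentation genes fell as a list in grade 2 by a median of 0.52, with 12 of 12 members lower (camera adjusted p = 3.21e-07; adjusted p = 0.16 with an estimated correlation). The class II genes H2-DMa, at -0.79 (SE 0.21), and H2-Eb1, at -0.61 (SE 0.20), passed only when adjusted over the list alone. The fibroblast and matrix list fell by a median of 0.53 (camera adjusted p = 0.000543; adjusted p = 0.41 with an estimated correlation), and no member passed. The epithelial to mesenchymal list fell by 0.30 (camera adjusted p = 0.0012; adjusted p = 0.16 with an estimated correlation). The alveolar type 2 list fell by 0.25 (camera adjusted p = 0.0124), the immediate early list fell by 0.25 (0.0124, 1 member when adjusted over the list alone), the endothelial list fell by 0.23 (0.0367) and the DNA replication list fell by 0.20 (0.0144). These calls were lost too, at adjusted p = 0.717, 0.48, 0.717 and 0.717 with an estimated correlation. With sex as a covariate the direction turned for the alveolar type 2 list (0.05, camera adjusted p = 0.532) and the endothelial list (0.09, 0.881). The hypoxia and glycolysis list rose by a median of 0.22 with 13 of 15 members higher (camera adjusted p = 0.0124; adjusted p = 0.511 with an estimated correlation). No list passed with fry. Leaving out 1 tumour ended the endothelial call without 8688T8 (-0.10), 8700T3 (-0.13) or 8565T4 (0.02), the DNA replication call without 8639T4 (-0.13) or 8565T3 (-0.13), and the immediate early call without 8688T8 (-0.14) or 8565T3 (-0.32). It ended the alveolar type 2 call without 8565T4 (-0.11) and the hypoxia call without 8639T4 (0.10). Other medians moved by over 1.5 times: fibroblast genes to -0.33 and antigen genes to -0.34 without 8565T4, DNA replication to -0.13 without 8700T1 and -0.11 without 8565T4, and hypoxia to 0.34 without 8688T10. Without 8639T4 the immediate early median was -0.41, the alveolar type 2 median -0.39 and the endothelial median -0.39, and without 8565T3 the alveolar type 2 median was -0.41.

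**Figure D3:**
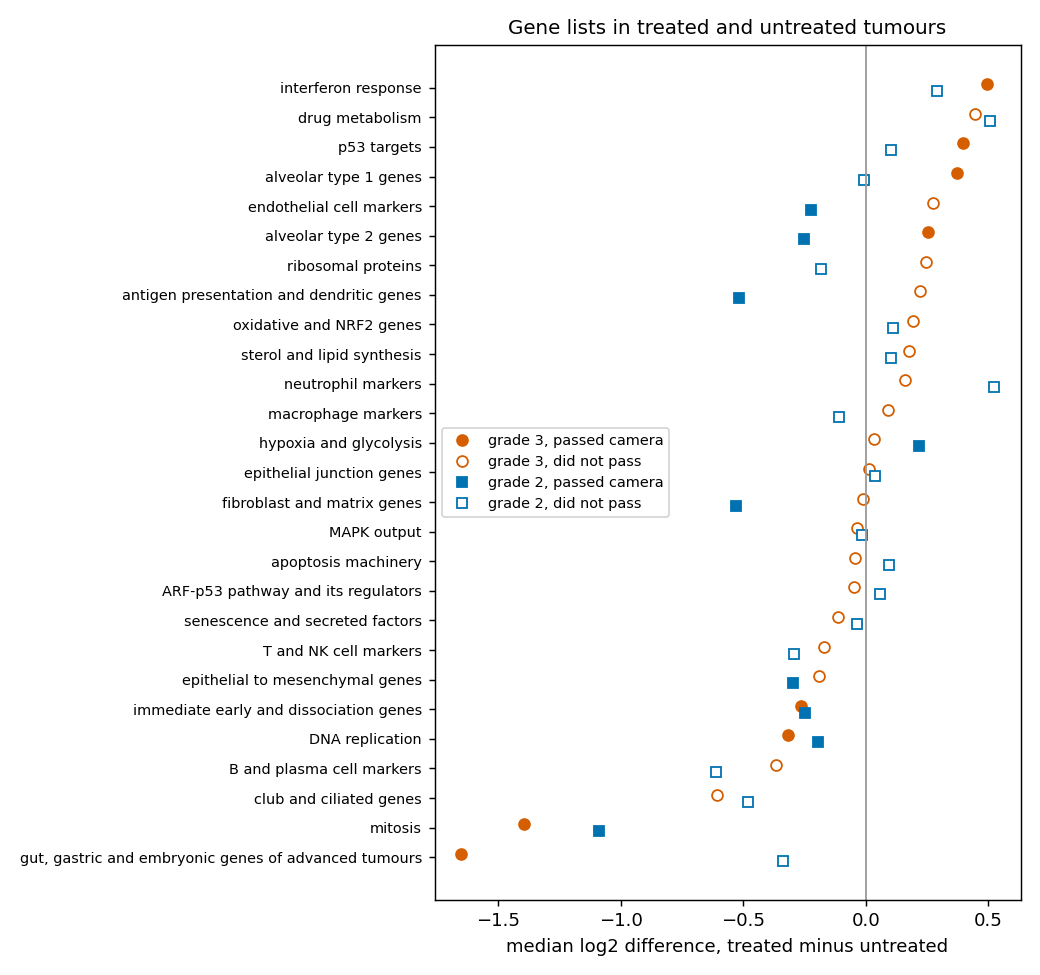
Median log2 difference, treated minus untreated, of each of 27 gene lists in grade 3 (circles) and grade 2 (squares). Filled symbols passed camera with a preset correlation between members. The mitosis list lies at -1.40 in grade 3 and -1.09 in grade 2, and the gut, gastric and embryonic list at -1.65 and -0.34.

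In grade 2 only 5 genes passed, and 510 had an unadjusted p under 0.05. Itgb3bp, which encodes a centromere protein, rose by 1.25 (SE 0.17, adjusted p = 0.00348) and the translation repressor gene Eif4ebp1 rose by 1.12 (SE 0.19, adjusted p = 0.022). The guanylate-binding protein gene Gbp2b fell by 5.02 (SE 0.80, adjusted p = 0.0166; not an exact size, since its treated mean of 2.77 lay below the array median), Hbb-b2 fell by 3.00 (SE 0.38, adjusted p = 0.00256) and the interleukin 1 receptor gene Il1r1 fell by 1.09 (SE 0.18, adjusted p = 0.0215). Hbb-b2 was the 1 gene that passed in both grades in the same direction, where independent lists of these sizes would share 0.00822 genes. Both comparisons rest largely on tumours of mouse 8688, so the treated sides are not independent, and treatment and mouse cannot be told apart. The fall of Hbb-b2 was read from 1 detected probe set. Its other probe set, below the array median on every array, differed by -0.70 in grade 3 and -0.50 in grade 2. The count was 37 without the animal term, 2 with sex as a covariate and 0 on animal means or without 8700 or 8565. The call was lost for Eif4ebp1 without 8688T8, 8639T4, 8700T3 or 8565T4, for Gbp2b without 8700T3, 8565T3 or 8565T4, and for Il1r1 without 8688T8, 8688T9, 8700T1, 8700T3 or 8565T4. Leaving out 1 tumour gave 3 genes without 8688T8, 13 without 8639T4, 2 without 8700T3 and 2 without 8565T4.

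Whether treatment acted differently in the grades was tested as an interaction. Treated grades were compared mostly within mouse 8688, and untreated grades mostly between mice, since only 8565 carried both. An interaction therefore cannot be told apart from differences between the untreated mice. No gene passed in limma, and 665 had an unadjusted p under 0.05. The smallest adjusted p, 0.127, belonged to Muc5b, with a difference of -2.92 (SE 0.53), and to the fetal liver gene Afp, with -2.69 (SE 0.48). Rtkn2 at 1.37 (SE 0.29), the matrix gene Fbln1 at 2.06 (SE 0.45) and Lgals4 at -1.54 (SE 0.34) had an adjusted p of 0.315. Muc5b and Fbln1 had group means below the array median, so these sizes are not exact. The interaction was 0.29 (SE 0.51) for Cdkn1a and 0.40 (SE 0.23) for Mdm2, with adjusted p of 0.864 and 0.581. Leaving out 8565T1 gave 14 genes, and leaving out 8688T2, 8688T5, 8639T4 or 8629T10 gave 1.

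By list, the p53 targets shifted more in grade 3 than in grade 2, by a median of 0.29 with 23 of 31 members above 0 (camera adjusted p = 0.012; adjusted p = 0.608 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. The call was lost without 8629T10 (median 0.24, camera adjusted p = 0.0515), without mouse 8700 (0.09, adjusted p = 0.292) and without mouse 8629 (0.17, adjusted p = 0.418). It was lost too with animal as a fixed block (0.04). The gut list differed by -1.28 (camera adjusted p = 6.31e-05), the alveolar type 1 list by 0.51 (0.00128), the alveolar type 2 list by 0.50 (6.31e-05) and antigen presentation by 0.58 (3.25e-06). With an estimated correlation the adjusted p was 0.578 for alveolar type 2 genes and 0.295 for the gut, type 1 and antigen genes, of which 3, 2 and 3 members passed when adjusted over the list alone. The interferon list differed by 0.42 (0.00213), endothelial markers by 0.48 (0.000497), ribosomal proteins by 0.35 (0.00261), hypoxia genes by -0.33 (0.00762) and mitosis by -0.30 (0.0135). Their adjusted p with an estimated correlation was 0.608, 0.608, 0.608, 0.578 and 0.769, and no list passed with fry. Adjusted over the list alone, 1 hypoxia gene passed and no member of the other lists here. The mitosis call was lost without 8688T2 (-0.28), 8688T9 (-0.33), 8688T10 (-0.27), 8565T1 (-0.20), 8629T12 (-0.23) or 8700T1 (-0.24), and the median was -0.70 without 8584T3 and -0.47 without 8639T4. Without mouse 8629 the mitosis median turned to 0.0099. The interferon call was lost without 8629T10 (0.20), the hypoxia call without 8639T4 (-0.28) and the ribosomal call without 8584T3 (0.28). With animal as a fixed block, which leaves 8565T1 as the only untreated grade 3 tumour, the interferon difference turned to -0.38. Without 8565T4 the medians were 0.32 for both alveolar lists, 0.31 for endothelial and -0.19 for hypoxia genes, without 8565T1 it was 0.81 for interferon genes, and without 8565T3 it was 0.54 for ribosomal proteins.

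Among untreated tumours, grade 3 differed from grade 2 most in gut genes. The gut, gastric and embryonic list rose by a median of 1.96 with 6 of 6 members higher (camera adjusted p = 5.61e-09; fry adjusted p = 0.002; adjusted p = 0.0544 with an estimated correlation). Hnf4a rose by 5.26 (SE 0.81, adjusted p = 0.0112), from 3.57 ± 1.30 (SD, n = 4) in grade 2 to 8.91 ± 1.40 (SD, n = 4) in grade 3, and Lgals4 rose by 1.66 (SE 0.26, adjusted p = 0.0112). All 6 members passed when adjusted over the list alone, among them the stomach genes Gkn2 at 3.36 (SE 1.12) and Ctse at 2.25 (SE 0.67). These are the 6 of 24 fixed members that passed the filter on low values, which could favour members high in untreated grade 3 tumours. The mean signal of the list was 8.88 ± 0.29 (SD, n = 4) in grade 3 and 6.28 ± 0.94 (SD, n = 4) in grade 2. Within mouse 8565, which carried both grades, it was 8.75 in the grade 3 tumour and 6.94 and 7.21 in the grade 2 tumours. The exact permutation p over animal means, 3 against 2, was 0.1, the smallest that design can give. Mouse 8565 had a mean on both sides, and the test took these as separate mice.

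In these untreated tumours 13 genes passed, 11 higher and 2 lower in grade 3, and 910 had an unadjusted p under 0.05. Muc5b rose by 3.17 (SE 0.41, adjusted p = 0.00357), the mast cell protease gene Mcpt2 by 5.31 (SE 1.04, adjusted p = 0.0449), the neutrophil surface gene Cd177 by 4.03 (SE 0.78, adjusted p = 0.0418) and Fxyd4 by 2.90 (SE 0.55, adjusted p = 0.033). Fbln1 fell by 1.95 (SE 0.35, adjusted p = 0.0248) and the growth factor gene Tgfb2 fell by 1.11 (SE 0.20, adjusted p = 0.0248). The same 4 untreated grade 3 tumours serve the treatment comparison in grade 3 and the interaction, so Muc5b and Lgals4 are not independent findings there. The same holds for lists called in several of these comparisons. The alveolar type 1 list mean was 9.74 in untreated grade 3 tumours. It was 10.24 in treated grade 3, 10.29 in treated grade 2 and 10.315 in untreated grade 2 tumours. For the interferon list these means were 7.19, 8.09, 8.045 and 7.91. Between the untreated grades, Cdkn1a differed by -0.26 (SE 0.39) and Mdm2 by -0.21 (SE 0.18), with adjusted p of 0.811 and 0.626. The lower group mean of Muc5b, Hnf4a, Mcpt2, Cd177 and Fbln1 lay below the array median, so these sizes are not exact. The call was lost for Mcpt2 without any 1 untreated tumour but 8584T3, for Cd177 without any but 8565T1 and 8629T10, for Fxyd4 without 8629T12, 8700T1, 8700T3 or 8565T4, for Fbln1 without 8629T12, 8700T3 or 8565T4, for Tgfb2 without 8700T1, 8700T3 or 8565T4, and for Lgals4 without 8565T4. The count was 111 without the animal term and 0 with animal as a fixed block, on animal means or without 8700. Leaving out 1 tumour gave 98 genes without 8565T1, 30 without 8629T10, 24 without 8584T3, 7 without 8629T12, 7 without 8700T1, 4 without 8700T3 and 2 without 8565T4.

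Among untreated tumours, the endothelial and alveolar lists were lower in grade 3 by camera with a preset correlation, and none of their members passed over all genes. The endothelial list fell by a median of 0.48 with 19 of 19 members lower (camera adjusted p = 1.78e-06; adjusted p = 0.534 with an estimated correlation). The alveolar type 1 list fell by 0.30 with 10 of 10 members lower (camera adjusted p = 7.11e-05; fry adjusted p = 0.0137; adjusted p = 0.164 with an estimated correlation). The alveolar type 2 list fell by 0.32 (camera adjusted p = 0.00117), the interferon list fell by 0.48 (8.82e-05) and the p53 targets fell by 0.21 (0.0175). For each of these the adjusted p was 0.615 with an estimated correlation. Adjusted over the list alone, 3 type 1 genes, 2 p53 targets and 1 interferon gene passed as lower. Antigen presentation fell by 0.35 (camera adjusted p = 0.000563), drug metabolism fell by 1.02 (0.0222) and ribosomal proteins fell by 0.19 (0.0343), with adjusted p = 0.534, 0.534 and 0.68 with an estimated correlation, and of their members only drug metabolism genes passed when adjusted over the list alone (4 lower, 1 higher). The mitosis list rose by 0.44 with 17 of 18 members higher (camera adjusted p = 0.000633; adjusted p = 0.615 with an estimated correlation). With animal as a fixed block, which leaves only mouse 8565, the interferon list turned to 0.19. Leaving out 1 tumour ended the p53 call without 8629T10 (-0.20), the drug metabolism call without 8629T10 (-0.74) or 8565T3 (-1.18), and the ribosomal call without 8584T3 (-0.105), 8700T1 (-0.15) or 8565T4 (-0.087). Without 8565T4 the medians were -0.24 for endothelial, -0.20 for type 1, -0.19 for type 2 and -0.21 for antigen genes. They were -0.53 for type 1, -0.50 for type 2 and -0.35 for ribosomal genes without 8565T3, and -1.10 for interferon and -0.55 for antigen genes without 8565T1. The median was -0.30 for interferon genes without 8629T10, 0.82 for mitosis without 8584T3 and -0.14 for p53 targets without 8700T1.

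Among treated tumours, grade 3 and grade 2 were close. All of these tumours but 8639T4 came from mouse 8688, while the untreated tumours came from several mice, so the comparisons of grade are not alike. No gene passed in limma, and no other fit called a gene. Of 7300 genes, 141 had an unadjusted p under 0.05, a smaller share than the 4.89% found with no change simulated. The estimate of the spread was shared with the untreated tumours, so the test may be too strict here. The 5 smallest p-values belonged to Rmdn1 at -0.42 (SE 0.11), Ebpl at 0.52 (SE 0.14), Ogfrl1 at 0.43 (SE 0.13), Zfp119a at -0.41 (SE 0.13) and Fbf1 at 0.41 (SE 0.13), each with an adjusted p of 0.997. A second detected probe set of Rmdn1 differed by 0.09, in the other direction. Cdkn1a differed by 0.04 (SE 0.32) and Mdm2 by 0.19 (SE 0.15). The p53 target list had a median of 0.05 (camera adjusted p = 0.545) and the mitosis list 0.10 (0.522). The gut list rose by a median of 0.79 with 6 of 6 members higher (camera adjusted p = 0.00341), antigen presentation rose by 0.30 (0.000219), the alveolar type 2 list rose by 0.14 (0.00716) and ribosomal proteins rose by 0.16 (0.0227). The club and ciliated list fell by 0.65 with 7 of 7 members lower (0.00169), immediate early genes fell by 0.20 (0.00126), drug metabolism fell by 0.27 (0.0333) and hypoxia genes fell by 0.10 (0.00543). With an estimated correlation these calls were lost, at adjusted p = 0.458 for the gut, antigen, club, immediate early and hypoxia lists, and adjusted p = 0.754, 0.813 and 0.498 for the alveolar type 2, ribosomal and drug metabolism lists. No member of these lists passed when adjusted over the list alone, and no list passed with fry. Only the gut and antigen calls held whichever tumour was left out. The club call was lost without 8688T9 (-0.39), the immediate early call without 8639T4 (-0.19), the alveolar type 2 call without 8688T3 (0.10) or 8688T8 (0.14), and the hypoxia call without 8688T11 (-0.098) or 8639T4 (-0.062). The ribosomal call was lost without 8688T1 (0.12), 8688T3 (0.10), 8688T8 (0.12) or 8688T10 (0.075), and the drug metabolism call without 8688T2 (-0.22), 8688T3 (-0.15), 8688T9 (-0.21), 8688T10 (-0.23), 8688T11 (-0.27) or 8639T4 (-0.17). The club median was -0.35 without 8688T11 and -1.01 without 8688T10, and the hypoxia median was -0.030 without 8688T9 and -0.22 without 8688T10.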

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

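In this part the 3 patterns weighed were picked after the group results were seen, with bounds set before the values per tumour, and 7 things came only after the results: the epithelial junction test, the rule that the RNA quality bound must be met by more than its SE, the look at the control transcripts by their 5' signals, the rule that a gap within 1 mouse must exceed the difference between mice, the mitosis value without the 2 tumours with a 3' excess, the rule that 8639T4 alone excludes nothing, and the rule on how many genes a second probe set must cover. Among the list shifts, 10 differed between the grades by camera's interaction test, and none held with an estimated correlation (adjusted p from 0.295 to 0.769). The median log2 differences, grade 3 minus grade 2, were 0.29 for p53 targets, -0.30 for mitosis, 0.50 for alveolar type 2, 0.51 for alveolar type 1, -1.28 for gut, 0.48 for endothelial, 0.58 for antigen presentation, 0.42 for interferon, -0.33 for hypoxia and 0.35 for ribosomal genes.

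Of 148 sets of values tested for a single tumour far from its group, 3 stood apart, where chance gives 7.4. Ctr9 was 9.66 in 8688T11, below the next treated grade 3 tumour at 9.95. The gut list was 9.31 in 8629T12 against 8.77 for the next untreated grade 3 tumour, and the interferon list was 7.72 in 8565T3 against 7.95 for the next untreated grade 2 tumour. Among 984 probe sets without a single gene name, which no comparison above used, 18 passed for treatment in grade 3 (3 higher, 15 lower), 7 for treatment in grade 2 and 4 for grade in untreated tumours.

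Other splits of the tumours were tried with the animal correlation held fixed. For treatment in grade 3, 1 of 100 splits, the real one, gave 34 genes, and the highest other gave 1, so chance can be excluded for a grouping of single tumours. It is not excluded between mice: only the real split sets all tumours of mouse 8688 against the others, and on animal means, 1 against 3, the count was 0. For treatment in grade 2, 2 of 35 splits gave at least the real 5 genes, so chance cannot be excluded. The other gave 220 and set the grade 2 tumours of 8688 with 8565T3 against 8639T4 and the rest, which points to a structure of the samples, whose nature was not tested. For grade in untreated tumours, 2 of 35 splits gave at least the real 13 genes, and the highest other, with 8565T3 in place of 8629T10, gave 66, which again points to a structure of the samples, so chance cannot be excluded. For the interaction and for grade in treated tumours, 0 genes passed and 100 of 100 splits gave as many, with highest others of 5 and 0.

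The mitosis list was lower in treated tumours, and a lower share of epithelial cells would lower epithelial genes too. The epithelial junction list had a median difference of 0.0125 in grade 3 (SE 0.042 over 18 members taken as independent), above the bound of -0.35 set from the mitosis shift. That argues against a lower share of epithelial cells only. The list cannot tell tumour cells from normal lung epithelium, so a lower share of tumour cells stays open. The alveolar type 1, alveolar type 2 and endothelial lists had medians of 0.37, 0.25 and 0.28 in grade 3. RNA quality stays open: the mean 3' minus 5' difference of 4 control transcripts was 0.253 higher in treated grade 3 (pooled SD 0.30) and 0.234 higher in treated grade 2 tumours (pooled SD 0.24), inside the bound set in advance only by 0.048 and 0.007, less than the SEs of 0.19 and 0.17. The 2 transcripts with detected 5' ends overlapped in both grades (0.375, exact permutation p = 0.481, and 0.085, p = 0.971), and the other 2, whose 5' signal lay below the array median on every array, cannot be weighed, although 1 was higher in treated tumours without overlap (0.74 and 0.65) and the other lower in grade 3 (-0.48). Without 8688T3 and 8639T4, the tumours with a 3' excess in the detected transcripts, the mitosis list still fell by 1.31 in grade 3 and by 0.80 in grade 2, so the excess in these 2 tumours does not by itself account for the fall. In 8639T4, the only treated tumour outside mouse 8688, the list lay at -1.18 from the lowest untreated grade 2 tumour, beyond the SD of 0.081 among the grade 2 tumours of 8688, but the bound set in advance was poorly chosen, since 8639T4 is 1 tumour with a 3' excess, so a property of 8688 and treatment cannot be told apart, and an effect of p53 restoration stays open, beside sex and animal.

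The genes called by treatment in grade 3 may in part reflect mouse 8688. Of 32 called genes without the sex genes, 8639T4 lay on the side of the grade 2 tumours of 8688 for 22 (68.8%). The exact 95% interval of 50.0% to 83.9% takes these genes as independent draws. All were read in the same tumour, and Cdca3, Nusap1 and Cdc20 share the mitosis list, so the interval is likely too narrow. It says nothing of the spread between tumours or mice. The share neither excludes nor requires a part of mouse 8688, so mouse and treatment cannot be told apart. Sequence variants under single probe sets stay open too: only 4 of the 34 called genes had a second detected probe set, Xist among them, and all 4 showed the difference there. The bound set in advance was met (lower 95% limit 39.8%), but it was poorly chosen, since 11.8% of the genes cannot speak for the rest.

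The gut and gastric list was high in untreated grade 3 tumours. In mouse 8565 the grade 3 tumour lay 1.53 above the higher of its grade 2 tumours, which were 0.27 apart. That met the bound set in advance, but it is 1 tumour, and the grade 2 means of 8565 (7.08) and 8700 (5.47) lay 1.61 apart, so grade and a difference between animals cannot be told apart. A single aberrant tumour is argued against by the lowest median difference when 1 untreated grade 3 tumour was left out, 1.64, against 1.96 with all. Grade itself may be the source, beside animal; how tumours were sampled at dissection stays open, as untested.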

How the results depend on the processing

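Leaving out mouse 8565, 8584, 8629 or 8700, the 2 tumours with a 3' excess or the 2 least correlated tumours was chosen after seeing the data; the cause of a change was not tested unless fewer samples or genes show it. Counts are given in the order treatment in grade 3 (34 as reported), treatment in grade 2 (5) and grade in untreated tumours (13), where each moved by over 1.5 times. They were 272, 37 and 111 without the animal term, 0, 0 and 0 on animal means, 12, 20 and 2 with only the groups compared, 64, 10 and 29 with no filter, 129, 1146 and 192 with array weights, and 63, 39 and 6 without the 2 least correlated tumours (8584T3 and 8629T12). Without 8565 they were 16, 0 and 6. With sex as a covariate, where treatment rests on 8639T4, the treatment counts were 10 and 2. With a floor of log2 5 the last 2 were 9 and 22, and with animal as a fixed block grade in untreated gave 0. Treatment in grade 2 gave 13 without the tumour of 8639, 10 without the tumours with a 3' excess and 0 without 8700. Without 8584 treatment in grade 3 gave 168 and grade in untreated 24, without 8629 they gave 10 and 3, and without 8700 grade in untreated gave 0. The interaction, 0 as reported, gave 1 with sex as a covariate, 38 with array weights, 1 without the tumour of 8639, 3 without 8565 and 1 without 8629. Grade in treated tumours gave 0 throughout. Grade in untreated tumours, 11 higher and 2 lower as reported, gave 11 and 4 with a further quantile normalisation and 11 and 5 with median centring.

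The p53 target shift in grade 3 passed in every alternative that tested it except with an estimated correlation (median 0.39, adjusted p = 0.213); array weights, the intensity trend and a log2 threshold were run on genes only. In grade 2 it passed with no filter (0.14), a floor of log2 5 (0.12) and without 8700 (0.19). The difference between grades did not pass with animal as a fixed block (0.042), with an estimated correlation or fry (0.29 each), without 8629 (0.17) or without 8700 (0.094). The p53 list score in grade 3 was 0.53 on animal means (exact permutation p = 0.25). Calls of other lists dropped to 0 with an estimated correlation and 5 with fry. Directions turned for the interferon list with animal as a fixed block (interaction -0.38, grade in untreated 0.19), for Ang3 (-0.40) and the immediate early list in grade 3 (0.15) and the alveolar type 2 (0.049) and endothelial (0.094) lists in grade 2 with sex as a covariate, and for the mitosis interaction without 8629 (0.0099). When 1 tumour was left out, the endothelial list in grade 2 ranged from -0.39 to 0.022, turning without 8565T4.

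Leaving out 1 tumour gave 16 to 168 genes for treatment in grade 3, 2 to 13 in grade 2, 0 to 14 for the interaction, 2 to 98 for grade in untreated and 0 for grade in treated tumours. The p53 shift ranged from 0.31 to 0.44 in grade 3, from -0.037 to 0.14 in grade 2 and from 0.21 to 0.34 for the difference, and the list score from 0.50 to 0.62. Of the genes and lists named, 231 gene values and 202 list values over all alternatives kept their direction but no longer passed, and 1144 and 1076 had the same outcome as reported, passing or not passing, in any direction where they did not pass. Another 16 gene values passed only in an alternative, and 1 gene value and 7 list values turned direction.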

Other observations

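Gbp2b, which encodes an interferon-induced GTPase, parted by mouse. It lay between 2.40 and 2.86 in all 10 treated tumours, those of 8688 and 8639T4 alike, and at 2.61 in the untreated tumour 8584T3. In the other untreated tumours it was 8.30, 8.15 and 8.27 in 8565, 7.96 and 8.08 in 8700 and 6.42 and 6.69 in 8629. Gbp2b was singled out after its values were seen. Hbb-b2 was 7.69 in 8639T4, within the 6.09 to 7.75 of mouse 8688 and below the lowest untreated tumour at 9.35.

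Mouse 8700 stood near the treated tumours in p53 targets and lay between the treated and the other untreated grade 2 tumours in mitosis. Its mean of the mitosis list was 6.87, against 7.64 for the grade 2 tumours of 8565 and 6.41 for those of 8688. The untreated grade 3 tumour 8584T3 had a Cdkn1a signal of 10.40 and a mitosis mean of 6.62, against Cdkn1a of 9.34 or less and mitosis of 7.88 to 8.45 in the other 3 untreated grade 3 tumours. These values were noticed in the data, and no test was run on them.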
